A study of Mus musculus with 4 samples.

How the data were processed

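RNA levels were measured on 4 Affymetrix gene arrays of B16-OVA cells, a mouse melanoma line that carries an ovalbumin transgene. Cells were transfected for 6 hours with Lipofectamine, a cationic lipid that carries nucleic acid into cells. Per the labels, 2 arrays came from mock transfected cells and 2 from cells transfected with AT90ES, which the group names and treatment text link to a double-stranded DNA of 90 base pairs. The treatment text was the same for all 4 arrays, so what the mock cells received is not given in the sources used here. Groups and replicate numbers were taken from the sample labels. Each array was made from 300 ng of total RNA, per the labels' protocols.

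The deposited values were log2 levels, 1 per probe and array, for 41345 probes. They had been made with RMA, per the submitters' processing notes, a method that corrects background, equalises the distributions of the arrays and summarises the signals of each probe set. The RMA software, its version and its settings were not given in the sources used here. The median log2 level was 4.91 and 4.85 on the mock arrays and 4.83 and 4.87 on the AT90ES arrays. Normalization of this kind removes any change shared by all genes, so every fold change is relative to the other genes on the array. For arrays the number of arrays limits the precision.

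Probes were named from a table of the platform's annotation. Of the probes, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Probes with several symbols or none named no gene. Of the probes with 1 symbol, 23328 were matched by gene ID to a RefSeq gene table of assembly GRCm38.p6, and 0 of these had another symbol there. No coordinates were used. Where a gene had more than 1 probe, which held for 1082 of the 22180 genes, the probe with the highest mean over the 4 arrays stood for the gene. Probes with several symbols entered no test of genes and were tested only where every probe was tested separately.

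AT90ES was compared with mock in limma 3.58.1 under R 4.3.3, with lmFit and eBayes, no covariate and no filter on dim probes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 22180 genes, with a threshold of 0.05. All adjusted p-values come from limma. The fit had 2 residual degrees of freedom per gene, to which the spread shared across genes added 3.70. The smallest two-sided p that an exact permutation test of 2 against 2 arrays can give is 0.333, so no such test could pass the threshold. Nothing in the labels says that replicates were separate cultures, and p-values then measure only the spread between these arrays, which could be technical.

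A set of 24 gene lists was fixed before the data were examined, covering interferons and their targets, DNA and RNA sensors, inflammation, antigen presentation, pigment cell genes, stress, cell cycle, metabolism, markers of other cell types, mitochondrially encoded genes and reference genes. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. With the preset value camera takes genes, not arrays, as its units, so its small p-values do not measure replication over arrays. The test was repeated with an estimated correlation, which rests on 2 residual degrees of freedom. Limma's fry was added, which tests whether a list's own genes move, on balance, in a single direction and does not compare the list with other genes. For each list, genes past the threshold were counted with adjustment over all genes and also adjusted over the list alone.

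Genes were named by a rule set at the same time. It took the 10 largest rises and the 6 largest falls among genes past the threshold with both AT90ES arrays on the same side of both mock arrays. In each list it took up to 4 members past the threshold, by size of change, or the 2 with the highest mean level where no member passed. It also took a set of genes of the DNA sensing, interferon, presentation and pigment pathways whatever their values. Gene models without an approved name were counted and not named. A gene named outside the rule is said to be so.

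The steps were tested on simulated data with 22180 genes, 200 of them changed, in 20 runs of this design. A further list of 20 genes was shifted in each run for the list test. Each gene's spread was limma's estimate after sharing across genes, which varies less between genes than the raw spread. The recovered shares may therefore be too high for the real data. Of genes changed 2-fold, 94.7% of those set higher and 93.5% of those set lower were recovered. At 1.5-fold the shares were 25.7% and 24.1%. Of 3196 calls, 249 (7.79%) were false, above the nominal rate. Calls among genes of the list test count in the 3196 and not among the false. Camera called a list of 20 genes shifted by 0.5 on the log2 scale in 20 of 20 runs and an unshifted list in 1 of 20. The simulated genes were drawn independently of each other, so these runs do not test camera on lists of correlated genes. Estimated correlations within the real lists ranged from -0.14 to 0.50.

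The alternatives were an intensity trend in the spread, a robust spread, the replicate number as a block, leaving out each array in turn, leaving out dim probes, the mean of a gene's probes, every probe tested separately, 3 further array scalings, a threshold of 0.1, and camera with ranks or an estimated correlation. A crossed pairing was added after the data were seen.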

Results

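The series held 4 arrays of RNA from B16-OVA mouse melanoma cells, 2 after mock transfection and 2 after transfection for 6 hours with the double-stranded DNA named AT90ES. Levels of 22180 genes were compared on the log2 scale of the deposited values. Across genes, Pearson's r was 0.992 between the mock arrays and 0.993 between the AT90ES arrays, and it lay between 0.987 and 0.989 across the groups. The genes of an array are not independent replicates. Between arrays of a group, 56 genes (mock) and 60 genes (AT90ES) lay more than 2-fold apart, against 154 to 218 between arrays of different groups. The first principal component held 50.8% of the variance and separated the groups.

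The comparison addressed which genes differ between melanoma cells given double-stranded DNA and mock transfected cells. What the mock cells received is not given, so effects of the DNA and of the transfection itself cannot be told apart. The largest measured rises were those of Ccl5, Ifit1, Ifih1 and Cxcl10. Ccl5, a chemokine that attracts T cells, rose from a log2 level of 5.85 ± 0.02 to 12.17 ± 0.05 (SD, n = 2 arrays per group), an 80.0-fold change. Cxcl10, another T cell chemokine, rose by 5.11 ± 0.12 on the log2 scale (SE), and Ifit1, which binds foreign RNA, rose by 6.05 ± 0.12. Of 22 measured genes on the list of p53 targets and DNA damage genes, 10 rose, led by Trp53inp1 at 3.12 ± 0.12. In limma's test 92 genes were higher and 0 lower in AT90ES cells, and 89 of the 92 changed at least 2-fold. Of the 92, 13 lay under the 95th percentile of olfactory receptor genes, a family taken as not expressed, on both mock arrays (percentile 4.85 to 5.07 over the 4 arrays), Mx2, Gbp7, Gbp3 and Igtp among them, and Ifih1 lay under it on 1 mock array. The rises of these genes were measured from a level near background, so their exact size and rank are uncertain. At an unadjusted p under 0.05 the numbers were 999 higher and 1017 lower, and the balance moved with the scaling, to 622 higher and 1885 lower with arrays centred on the reference genes and 1078 higher and 705 lower with arrays centred on their median. With an intensity trend in the spread, limma called 431 higher and 162 lower, and with dim probes left out 160 higher and 6 lower.

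**Figure D1:**
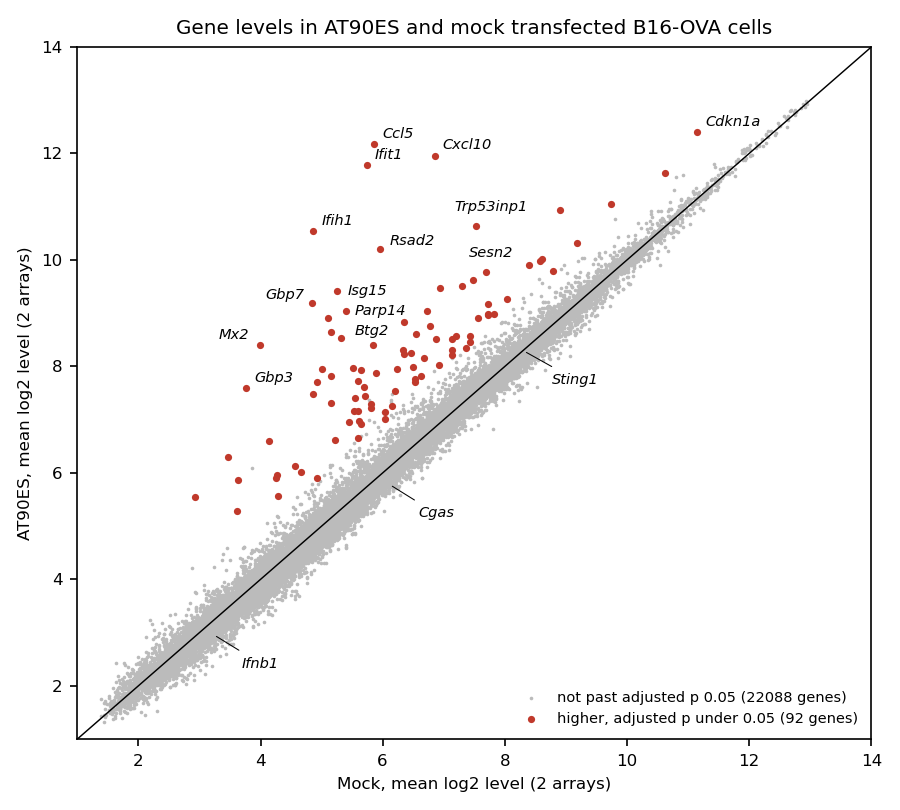
Mean log2 level of each of 22180 genes on the 2 AT90ES arrays (vertical axis) against the 2 mock arrays (horizontal axis), with the line of equal levels. The 92 genes past adjusted p 0.05 (red) all lie above the line, with Ccl5 at 5.85 and 12.17, while Ifnb1, Cgas and Sting1 are among the genes that did not pass.

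Antiviral interferon-stimulated genes formed the largest group of changed genes. Of 47 measured members, 26 rose, 0 fell and 21 did not pass. Adjusted over the list alone, 34 were higher and 1, Oas2, named after its value was seen, was lower at -0.33. Mx2, a GTPase, rose by 4.41 ± 0.13 (adjusted p = 0.00031). Rsad2, which encodes the antiviral enzyme viperin, rose by 4.25 ± 0.12. Isg15, a ubiquitin-like modifier, rose by 4.16 ± 0.14 and Parp14, an ADP-ribosyltransferase, by 3.64 ± 0.16. The median log2 fold change of the list was 1.32, with a camera adjusted p = 5.04e-50 and an adjusted p = 0.0766 with an estimated correlation. Several members have close relatives on the array, and levels of such genes are uncertain where probes hybridise to more than 1 of them: Ifit3b rose by 2.62 while Ifit3 stood at 0.02, a pair chosen after its values were seen, and Ifit3b lost its call in 1 of the 4 fits that left out an array.

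Interferon-inducible GTPases, which act against pathogens inside cells, had 4 of 13 measured members higher, 0 lower and 9 not passed, with 7 higher adjusted over the list alone. Gbp7 rose by 4.36 ± 0.17, Gbp3 by 3.84 ± 0.19, Irgm1 by 2.45 ± 0.12 and Igtp by 1.68 ± 0.12. The median was 0.57, with a camera adjusted p = 1.95e-13 and an adjusted p = 0.12 with an estimated correlation. Among 17 interferon signalling factors, 2 rose, 0 fell and 15 did not pass, with 6 higher adjusted over the list alone. The risen pair was Stat2 at 1.98 ± 0.12 and Irf9 at 1.26 ± 0.13, whose proteins act together in the transcription factor complex downstream of type I interferon. Irf7, the amplifier of interferon production, had a log2 fold change of 0.35 (adjusted p = 0.471). The list median was 0.21, with a camera adjusted p = 3.76e-07 and an adjusted p = 0.221 with an estimated correlation.

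The interferon genes themselves did not pass. Of 16 measured type I and III interferons, 0 were higher and 0 lower, in limma, also adjusted over the list alone, at an unadjusted p under 0.05 and with an intensity trend, and camera gave an adjusted p = 0.836. Ifnb1, the first interferon made in most cells that sense DNA, had a log2 level of 3.22 ± 0.10 in mock and 2.97 ± 0.11 in AT90ES cells (SD, n = 2). Its log2 fold change of -0.25 had an adjusted p = 0.632, and its levels lay in the range of olfactory receptor genes on the same arrays. Ifna1 stood at 0.08 and Ifnl2 at -0.13, neither past the threshold.

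Of 26 measured nucleic acid sensors and adaptors, 3 rose, 0 fell and 23 did not pass, with 4 higher adjusted over the list alone. The 3 were the RNA sensors of the RIG-I family: Ifih1 at 5.69 ± 0.24, Ddx58 at 3.49 ± 0.13 and Dhx58 at 1.62 ± 0.13. The DNA sensors and their partners did not pass. Cgas, the cytosolic DNA sensor that makes cyclic GMP-AMP, had a log2 fold change of -0.31, Sting1, its adaptor, 0.01, Tbk1 0.21, Irf3 0.04, Zbp1 0.43 and Aim2 0.19. Aim2 had a mean level of 3.20 in mock and 3.39 in AT90ES cells. On each array it lay under the 95th percentile of olfactory receptor genes, so a change near background could go unseen. The list median was 0.07, with a camera adjusted p = 0.00946 and an adjusted p = 0.5 with an estimated correlation. Without mock replicate 1 the adjusted p was 0.0883 and the median -0.00095 (range of p over the alternatives 0.000786 to 0.5), with arrays centred on the reference genes the median was -0.015, and with camera on ranks the adjusted p was 0.202.

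Chemokines and cytokines had 3 of 30 members higher, 0 lower and 27 not passed, with 6 higher adjusted over the list alone. Besides Ccl5 and Cxcl10, Csf1, the growth factor of macrophages, rose by 2.32 ± 0.13. The median was 0.14, with a camera adjusted p = 7.38e-06 and an adjusted p = 0.248 with an estimated correlation. Among 23 NF-kappaB feedback and target genes, 3 rose, 0 fell and 20 did not pass. Adjusted over the list alone, 6 were higher and 1, Birc3, named after its value was seen, was lower at -0.48. Nfkbie rose by 1.97 ± 0.12, Nfkb2 by 1.37 ± 0.12 and Nfkbia, the inhibitor that holds NF-kappaB in the cytoplasm, by 1.35 ± 0.13. Tnfaip3, another feedback inhibitor, stood at 0.46 (adjusted p = 0.513). The median was 0.21, with a camera adjusted p = 3.44e-07 and an adjusted p = 0.138 with an estimated correlation.

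MHC class I presentation had 2 of 19 measured members higher, 0 lower and 17 not passed, with 5 higher adjusted over the list alone. Tapbp, which loads peptide onto class I molecules, rose by 2.21 ± 0.13 and Tap1, a subunit of the peptide transporter, by 1.58 ± 0.16. The other, dimmer probe of Tapbp had a log2 fold change of 1.29 (adjusted p = 0.247 with every probe tested separately, against 0.0442 for the brighter probe). B2m, the class I light chain, was already at a log2 level of 11.44 in mock cells, and the log2 fold change of B2m was 0.30 (adjusted p = 0.546, and 0.00259 to 0.861 over the alternatives, passing with an intensity trend). The median was 0.21, with a camera adjusted p = 3.76e-07 and an adjusted p = 0.138 with an estimated correlation. Among 14 immune checkpoint ligands and costimulators, 1 rose, 0 fell and 13 did not pass, with 2 higher adjusted over the list alone. The risen gene was Cd274, which encodes PD-L1, at 1.49 ± 0.12, and the list had a camera adjusted p = 0.795.

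The p53 target and DNA damage list had 10 of 22 measured members higher, 0 lower and 12 not passed, and 19 were higher adjusted over the list alone. With arrays centred on the reference genes 6 were higher. Trp53inp1 was followed by Btg2, an antiproliferative gene, at 2.56 ± 0.12, Plk2, a stress-responsive kinase, at 2.55 ± 0.16, and Sesn2, an inhibitor of growth signalling, at 2.08 ± 0.11. Cdkn1a, the inhibitor of cyclin-dependent kinases, and Mdm2, the ubiquitin ligase that degrades p53, were named after their values were seen and rose by 1.26 and 1.39, calls that held in 0 of the 4 fits that left out an array (adjusted p up to 0.202 and 0.171). The median was 0.95, with a camera adjusted p = 1.45e-28, an adjusted p = 0.0766 with an estimated correlation and a fry adjusted p = 0.00178 for a shift of the list's own genes in a single direction.

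**Figure D2:**
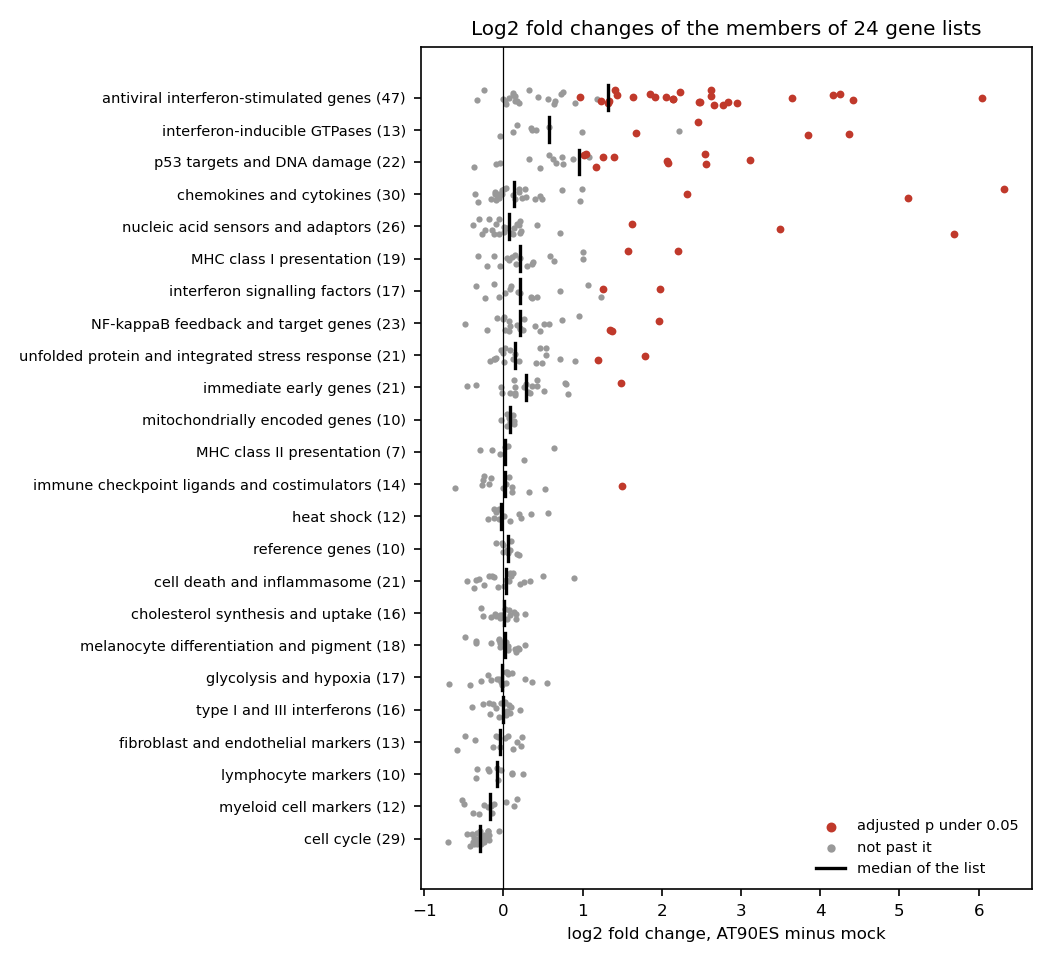
Log2 fold change (AT90ES minus mock, horizontal axis) of each measured member of 24 gene lists, with the number measured in parentheses, members past adjusted p 0.05 in red and the list's median as a bar; vertical scatter within a list has no meaning. The median was 1.32 for antiviral interferon-stimulated genes, 0.95 for the p53 target and DNA damage list and -0.29 for the cell cycle list, of which no member passed alone.

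Genes of the unfolded protein and integrated stress response had 2 of 21 members higher, 0 lower and 19 not passed, with 8 higher adjusted over the list alone. The risen pair was Ddit4, an inhibitor of mTOR signalling, at 1.79 ± 0.13 and Chac1, which degrades glutathione, at 1.20 ± 0.12. The median was 0.14, with a camera adjusted p = 1.35e-06 and an adjusted p = 0.297 with an estimated correlation. Of 21 immediate early genes, 1 rose, 0 fell and 20 did not pass. Adjusted over the list alone, 6 were higher and 1, Myc, named after its value was seen, was lower at -0.45. The risen gene was Atf3, a stress-induced transcription factor, at 1.48 ± 0.12. The median was 0.29, with a camera adjusted p = 3.76e-07 and an adjusted p = 0.248 with an estimated correlation. For immediate early genes and for MHC class I presentation fry gave an adjusted p = 0.0597.

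The cell cycle list fell as a set, with a camera adjusted p = 9.18e-13 and an adjusted p = 0.242 with an estimated correlation. All 29 measured members had negative log2 fold changes, with a median of -0.29, and the list's camera call and direction held in each scaling tried and without each array. Limma called 0 members lower alone, against 12 at an unadjusted p under 0.05 and 14 with an intensity trend, and adjusted over the list alone 1 was lower, Cdc6, a replication licensing factor, at -0.69. Mki67, a marker of proliferating cells, stood at -0.22 and Pcna, the replication clamp, at -0.06. The largest fall of any gene, that of Cdca7, was -0.99 and did not pass (adjusted p = 0.0622); Cdc6 and Cdca7, both named after their values were seen, passed as lower with dim probes left out.

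Pigment cell genes did not pass, with 0 of 18 members higher or lower in limma, 2 lower at an unadjusted p under 0.05 and 3 lower with an intensity trend, and a camera adjusted p = 0.98. The log2 fold change of Mitf, the master regulator of melanocytes, was -0.34 (adjusted p = 0.469), and with an intensity trend its adjusted p was 0.00483 (range over the alternatives 0.00483 to 0.817). Tyr, the rate-limiting enzyme of melanin synthesis, stood at -0.05, Tyrp1 at 0.01 and Dct at -0.04. MHC class II presentation (7 members, Ciita at 0.06 and H2-Eb1 at -0.29) had a camera adjusted p = 0.759. Cell death and inflammasome genes (21 members, Casp8 at 0.09 and Mcl1 at 0.01) had 0.679, with 1 higher adjusted over the list alone and an upward fry adjusted p = 0.0297. Cholesterol genes (16 members, Insig1 at 0.27 and Hmgcs1 at 0.16) had 0.839, with Insig1 past the threshold under an intensity trend (adjusted p = 0.0164, range over the alternatives 0.0164 to 0.879). Glycolysis and hypoxia genes (17 members, Gapdh at -0.02 and Pkm at -0.06) had 0.98, with 1 higher and 1 lower adjusted over the list alone. Heat shock genes (12 members, Cryab at 0.22 and Hspa8 at 0.00) had 0.679.

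Markers of other cell types did not pass. Their mean levels lay above that of the median gene for 5 of 12 myeloid, 1 of 10 lymphocyte and 4 of 13 fibroblast and endothelial markers. The 12 myeloid markers had a median of -0.17 and a camera adjusted p = 0.0568, with Cd68 at -0.15 and Fcer1g at -0.31. That p was 0.0125 without AT90ES replicate 2, 0.0394 without mock replicate 2 and 0.0355 with arrays centred on their median, and it ranged from 0.0125 to 0.639 over the alternatives. The 10 lymphocyte markers (Cd79b at -0.03, Nkg7 at -0.20) had 0.57 and the 13 fibroblast and endothelial markers (Col1a1 at -0.06, Col1a2 at -0.14, and 0.40 by its dimmer probe) had 0.856. Mitochondrially encoded genes (10 members, ND4 at 0.05 and CYTB at 0.04) had 0.142, with 0.000705 under an intensity trend, 0.0398 on ranks and a range of 0.000705 to 0.748 over the alternatives. Reference genes (10 members, Ywhaz at 0.08) had a median of 0.05, a camera adjusted p = 0.415 and an upward fry adjusted p = 0.0484. Signs differed between measures in 5 lists that did not pass. Interferons had a median of 7.65e-05, a mean of -0.04 and a downward test. Pigment genes had a median of 0.02, a mean of -0.02 and a downward test. Cholesterol genes had a median of 0.0032, a mean of -0.0022 and an upward test. Glycolysis genes had a median of -0.02, a mean of -0.03 and an upward test. Heat shock genes had a median of -0.03, a mean of 0.07 and an upward test.

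**Figure D3:**
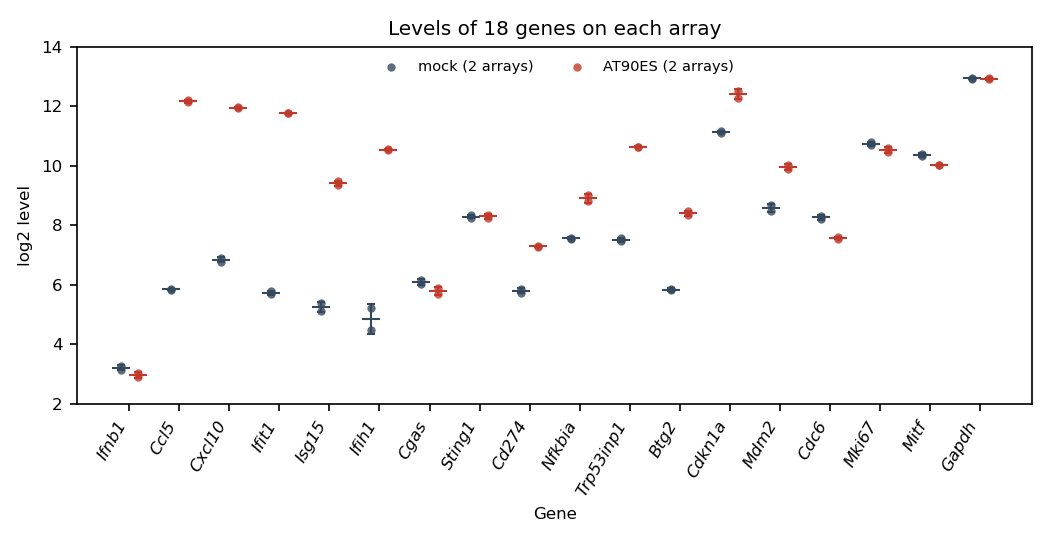
Log2 level (vertical axis) of 18 genes on each mock (blue) and AT90ES (red) array, with the mean of 2 arrays as a horizontal line and the SD as a bar; some genes were chosen for display after their values were seen. Ccl5 and Ifit1 lie at 12.17 and 11.78 in AT90ES cells, while Ifnb1 lies at 2.97 and Sting1 at 8.30, near their mock levels of 3.22 and 8.29.

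Counts depended on each array: the genes called higher numbered 47 without mock replicate 1, 44 without mock replicate 2, 32 without AT90ES replicate 1 and 35 without AT90ES replicate 2, where the lone array is assumed to vary like the other group, and interferon-stimulated members numbered 17, 14, 14 and 15 and p53 members 5, 5, 4 and 4. Of the 30 named genes past the threshold, 20 passed in all 4 of these fits, while Igtp, Ddit4, Dhx58, Atf3, Cd274, Tap1, Nfkb2, Nfkbia, Irf9 and Chac1 did not.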

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

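The test of every probe was planned before the data were examined, and the attention to probes of several genes came after its result was seen. Among the 1814 probes that the annotation assigns to several genes, which named no gene in the comparison, 2 were higher in AT90ES cells when every probe was tested separately with limma. Their log2 fold changes were 2.94 (adjusted p = 0.0396) and 2.83 (adjusted p = 0.0205), and what drew attention to them was a signal above mock outside the probes used for genes. The annotation gives Cyren and Tmem140 for the first probe and Gbp2 and Gbp2b for the second, all named here outside the rule. Gbp2 is on the list of interferon-inducible GTPases but was not among its 13 measured members. No explanation was tested for either probe.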

How the results depend on the processing

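The crossed pairing was chosen after the data were seen, and so was the rule that a change of sign counts as a reversal only where the value passed the threshold before or after. Under a stricter rule, 34 of 867 values of named genes and 38 of 311 list medians changed sign, the largest at 0.14 and 0.21. Under the rule used, 2 did, both medians of the nucleic acid sensor list: -0.00095 without mock replicate 1 (up to 0.0893 without another array) and -0.015 with arrays centred on the reference genes, where camera still passed upward. For named genes past the threshold, 349 comparisons stayed past it and 40 did not; for those not past it, 475 stayed and 3 passed. For lists past the threshold the other 141 stayed; for those not past it 162 stayed and 6 passed. These list counts leave out camera on ranks, where the nucleic acid sensor list lost its call (adjusted p = 0.202), and with an estimated correlation, where all 11 did.

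Genes higher in AT90ES cells numbered 431, and lower 162, with an intensity trend in the spread, and 160 and 6 with dim probes left out, where fewer genes were tested. With every probe tested separately, 30 probes were higher, all at least 2-fold, 28 of them probes that stood for a gene. More tests were made there, and the spread shared across probes added 2.83 degrees of freedom, against 3.70 for genes. One at a time, centring arrays on their median and a threshold of 0.1 each gave 1 lower gene. Genes higher numbered 127 with arrays centred on their median and 71 with arrays centred on the reference genes. Without each array in turn, genes higher, and those at least 2-fold, numbered 32 to 47, with fewer arrays in the fit. With an estimated correlation, camera called 0 of 24 lists, against 11 with the preset correlation and 11 on ranks, and the test then rests on 2 residual degrees of freedom. The estimate was 0.0129 for interferon-stimulated genes, near the preset 0.01, and -0.04 for the p53 list. For these lists the lost calls thus go with the fewer degrees of freedom, not with a much higher correlation. A robust spread left camera untouched, since camera does not use it, and with dim probes left out too few lymphocyte markers remained for a test. How much each difference between the settings moved the counts was not tested.

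The replicate numbers did not pair the arrays: the differences between replicates of the 2 groups correlated at -0.22 across genes. The second principal component (30.0% of the variance) put mock 1 beside AT90ES 2 and mock 2 beside AT90ES 1. The third (19.2%) put equal replicate numbers together. Pearson's r was 0.9890 and 0.9892 for the crossed pairs, against 0.9868 and 0.9883 for equal numbers. Whether a batch lies behind this was not tested. With the replicate block 85 genes were higher, of which 80 were among the 92, and 12 lists passed, the myeloid markers among them (adjusted p = 0.0396, range over the alternatives 0.0125 to 0.639). With the crossed pairing, chosen after seeing the data, 59 were higher, all at least 2-fold, 5 p53 list members among them, and 12 lists passed. Dim probes limit what can be seen: a low-expressed gene near the array floor can change without a call.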

Other observations

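In this part the test of Ifnb1 against olfactory receptor genes was chosen only after the result was seen, and the genes of the next paragraph were chosen after their values were seen.

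Of the 92 genes higher in AT90ES cells, 35 belonged to no list. Several act on RNA or against viruses. Apobec1, a cytidine deaminase that edits RNA, rose by 2.14, Znfx1, a helicase-like antiviral protein, by 1.89, Trim26 by 1.49, Rnf213 by 1.18 and Zc3hav1, which binds viral RNA, by 1.13. Others are known from stress responses or nutrient uptake. Slc7a11, the cystine transporter, rose by 1.74 (1.13 by its dimmer probe), Nupr1, a stress-induced nuclear protein, by 1.72 and Slc19a2, a thiamine transporter, by 1.64. Atm, the kinase that responds to DNA breaks, rose by 1.23 and Ddias by 1.25. Zfp36, which destabilises inflammatory mRNA, rose by 1.11, Tgfb2 by 1.08, and Hdc, which makes histamine, by 1.69. Of the genes named here Znfx1 alone passed in all 4 fits that left out an array, as did 30 of the 92 in all, and Hdc was near background on both mock arrays. No test of a theme was made on these genes.

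Of 22 measured members of the p53 target and DNA damage list 10 were higher in AT90ES cells, as were 26 of 47 interferon-stimulated genes. Both lists passed camera, each with an adjusted p = 0.0766 with an estimated correlation. Choice of the brightest probe is argued against, since 0 of the measured p53 list members had more than 1 probe. A general stress of the transfected cells may contribute and stays open. The unfolded protein and integrated stress response list had a median of 0.14, under the 0.47 (0.5 times the p53 median) set beforehand, and passed camera, but with an adjusted p = 0.297 with an estimated correlation, while heat shock genes had a median of -0.03.

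No gene passed as lower, although the cell cycle list fell as a set by camera (adjusted p = 0.242 with an estimated correlation). Array scaling that lifts the AT90ES arrays was tested only for a lift of the size the reference genes show. Centring on them moved the median of all genes from -0.021 to -0.108, and 0 genes then passed as lower. The same centring took the genes called higher from 92 to 71, so calls could move with it. A lift of the size the reference genes show thus brought out no lower call. A larger lift was not tested, so scaling stays open beyond that size. At an unadjusted p under 0.05 in limma, lower genes went from 1017 to 1885 with this centring. The median of all genes itself is held near 0 by RMA and decides nothing. A candidate explanation is the single prior spread shared by bright and dim probes, since 162 genes passed as lower with an intensity trend. That the trend was the better model was not tested. The falls were also small. At any p, 0 genes fell at least 2-fold, against 109 that rose, and the largest fall was -0.99. In the simulated data 24.1% of 1.5-fold falls were recovered, so most falls of that size would go uncalled.

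Interferon genes did not pass, while 26 of 47 interferon-stimulated genes rose. A common floor near the olfactory receptor levels did not hold for every interferon probe. On an AT90ES array 6 of 16 interferon genes lay above the array median. On all 4 arrays 5 lay above the 95th percentile of 1088 olfactory receptor genes. Each probe can have its own background, however, so these levels cannot show that the genes are expressed. Ifna1, for example, stood at 7.38 in mock and 7.46 in AT90ES cells. The comparison does not cover the other interferon genes. For Ifnb1, whose level was at most 0.33 above the olfactory receptor median of its array, an unseen rise near the floor and no rise at 6 hours cannot be told apart, because its levels of 2.89 to 3.29 lay near those medians of 2.90 to 2.98. An earlier rise that had ended may also account for it, and no other time point was analysed here.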
